A study of Naumovozyma castellii and Vanderwaltozyma polyspora and Candida albicans with 9 samples.

How the data were processed

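Small RNA libraries of 5 yeast species were compared, with 1 library in each of 9 groups taken from the sample titles. The deposited files hold raw read counts, that is, distinct 36-nt sequences with the number of reads of each, without alignment or normalization. Per the labels, total RNA came from log-phase cultures at 25 °C or 30 °C and was selected at 18 to 30 nt. S. castellii WT, the pair of Ago1 IP and input, and each knockout came from different strains, per the labels. How the authors called bases and collapsed reads is not given in the sources used here.

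From the counts, the 3′ adapter TCGTATGCCGTCTTCTGCTTG was removed at its leftmost start, comparing 9 bases without mismatches and asking for at least 6 bases at the read end. An uncalled base in the read counted as a match to the adapter. Uncalled bases were in 41.1% of raw reads in S. castellii WT and in at most 1.87% in every other library. Inserts of 18 to 30 nt without uncalled bases were kept. Reads within 2 edits of the synthetic size markers AGCGTGTAGGGATCCAAA and GGCATTAACGCGGCCGCTCTACAATAGTGA were left out. The adapter and marker sequences were recognised in the reads, since the labels do not give them. Structural RNA meant a sense match with at most 2 mismatches to 1 of 398 rRNA, tRNA, snRNA, snoRNA and related genes of the S. cerevisiae S288C annotation (assembly R64). Structural RNA that has diverged further from S. cerevisiae, or that reaches past the end of a gene, stays among the other reads. Reads that hold 16 bases of 1 of 17 mammalian microRNAs, a list written from general knowledge after the data were seen since no microRNA reference was given, were counted but kept, and their sequences are not printed. Perfect matches to the S288C genome were found on both strands and classed by annotation.

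For each library the share of 22 to 23 nt reads, the share of 5′ U among them, and the share of distinct sequences (at least 2 reads) with a partner of equal length at a 2-nt 3′ overhang were computed. Other offsets from -8 to 8 served as the background of the last measure. Sequences of 21 to 24 nt with at least 100 reads over both libraries were compared by reads scaled to the small RNA reads of each library (RPM), and counted when at least 4-fold apart. With no S. castellii, K. polysporus, C. albicans or S. bayanus genome given, sequences of 21 to 24 nt with at least 3 reads and outside structural RNA were joined by exact overlaps of 17 bases into groups of at least 30 nt. The S. castellii groups were built from the 5 libraries with that label, so reads of another species in them could form groups too. Groups were compared with translated S. cerevisiae proteins by blastx (E at most 0.0001). A group is a stretch of overlapping reads, not an annotated locus.

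No test was run, since each group has 1 library. Shares have exact 95% Clopper-Pearson intervals, ratios have the interval conditional on the sum of both counts, and a count of 0 was set to 3 reads for ratios. Reads are not independent molecules. Depth ran from 98076 to 1997174 small RNA reads per library, so 0 reads allow from 1.502 to 30.6 RPM.

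The comparisons, the window of 22 to 23 nt, the thresholds above and most alternatives were chosen before the data were examined; removing size markers, the structural RNA rule, the 17-base overlap and the check of species labels were chosen after. Text names sequences and groups by a fixed rule. It allows, per library, the 5 most abundant 22 to 23 nt sequences that start with U and the 3 most abundant of any length. Per comparison it allows the 5 lowest and 5 highest sequences and the 12 lowest and 12 highest groups, and lists of genes as classes; fewer are printed. The 655-nt and 843-nt groups and those resembling mitochondrial genes were also named for their read numbers or class, after their values were seen. The lists were rRNA, tRNA, snRNA and snoRNA, retrotransposons, Y′ helicases, ribosomal proteins, glycolysis, histones, heat shock, sense and antisense protein-coding matches and intergenic matches. Inverted repeats of the genome and convergent 3′ ends were not analysed here, since they need the S. castellii genome.

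Alternatives covered counting each sequence once, leaving out rare, abundant, structural or conserved sequences, other length windows, denominators and scalings, the input as comparator, other thresholds and trimming rules. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9, edlib 1.3.9.post1, bwa 0.7.19 and BLAST+ 2.17.0 were used. Trimming, pairing and joining were tested on simulated data: 100% of 5000 simulated reads got their true insert length, 100% of 5000 random reads got no insert, 400 of 400 planted sequences among 2200 were found to have a partner, and a region of 600 nt tiled with 193 sequences was rebuilt to 599 nt. In counts simulated from the input library, 1221 sequences were tested, 200 of them set 8-fold lower. Of the changed sequences 99.5% were called at least 4-fold lower, no unchanged sequence was, and 94.9% of intervals of unchanged sequences held the simulated ratio. Both simulated libraries were drawn from the same counts with counting error only. These values therefore do not cover differences between strains or preparations. Between the real WT and input libraries, 106 of 708 sequences were at least 4-fold lower in WT and 60 at least 4-fold higher.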

Results

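Small RNAs selected at 18 to 30 nt were sequenced from log-phase cultures of 5 budding yeast species in 9 libraries, 1 per group. The S. castellii libraries were labelled wild type (WT), Ago1 IP (RNA bound to the Argonaute protein Ago1), input, ago1 knockout and dcr1 knockout, where DCR1 codes for the Dicer enzyme. The other libraries were labelled WT of K. polysporus, C. albicans, S. cerevisiae and S. bayanus. Raw depth ran from 510234 reads in S. castellii WT to 4342058 in S. bayanus. After trimming, small RNA reads numbered 262801 in S. castellii WT, 1167349 in Ago1 IP, 1256202 in the input and 1018757 in the dcr1 knockout. They numbered 840150 in K. polysporus, 1997174 in C. albicans and 1083179 in S. bayanus. The library labelled ago1 knockout held 98076 such reads and the library labelled S. cerevisiae WT held 429693. Read numbers scaled to the small RNA reads of a library are given as RPM. No difference below has a replicate check, and intervals in parentheses are exact 95% Clopper-Pearson intervals that cover counting error only.

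The knocked-out genes themselves, AGO1 and DCR1, were not analysed here, because no S. castellii sequence was given. The sequences of a pair of libraries went against their species labels. Among reads of 24 to 30 nt outside structural RNA, 50% (48.3 to 51.7) matched the S. cerevisiae genome perfectly in the library labelled ago1 knockout, against 3.99% (3.72 to 4.29) in the library labelled S. cerevisiae WT. Reads of 21 to 24 nt outside structural RNA were joined into 980 groups of overlapping sequences built from the S. castellii libraries. These groups held 66.3% (65.9 to 66.6) of such reads in the library labelled S. cerevisiae WT, 10.1% (8.85 to 11.4) in the library labelled ago1 knockout, 70.1% in S. castellii WT, 60.2% in the input and 12.3% in S. bayanus. Directions given for both libraries below therefore rest on labels that their sequences contradict.

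The length of Dicer products was the first question. Reads of 22 to 23 nt made up 47.2% (47.0 to 47.4) of small RNA reads in S. castellii WT, and 79.6% (79.4 to 79.8) once matches to structural RNA were left out. The most frequent length there was 23 nt, with 59.4% of the reads outside structural RNA. In these 22 to 23 nt reads the 5′ base was U in 47.6% (47.3 to 47.9). Outside structural RNA it was U in 39.2% at 18 to 20 nt and in 52.6% (50.7 to 54.5) at 25 to 30 nt. A 5′ U was thus not particular to 22 to 23 nt in this library, where the 25 to 30 nt class held 2755 reads. Of the 11304 distinct 22 to 23 nt sequences with at least 2 reads, 22.6% (21.8 to 23.4) had a partner that pairs with 2-nt 3′ overhangs, against a mean of 16.95% and a highest value of 19.7% over other offsets from -8 to 8. The most abundant sequence, AGGATATGAAAGAAATGATGCTT, had 1500 reads.

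**Figure D1:**
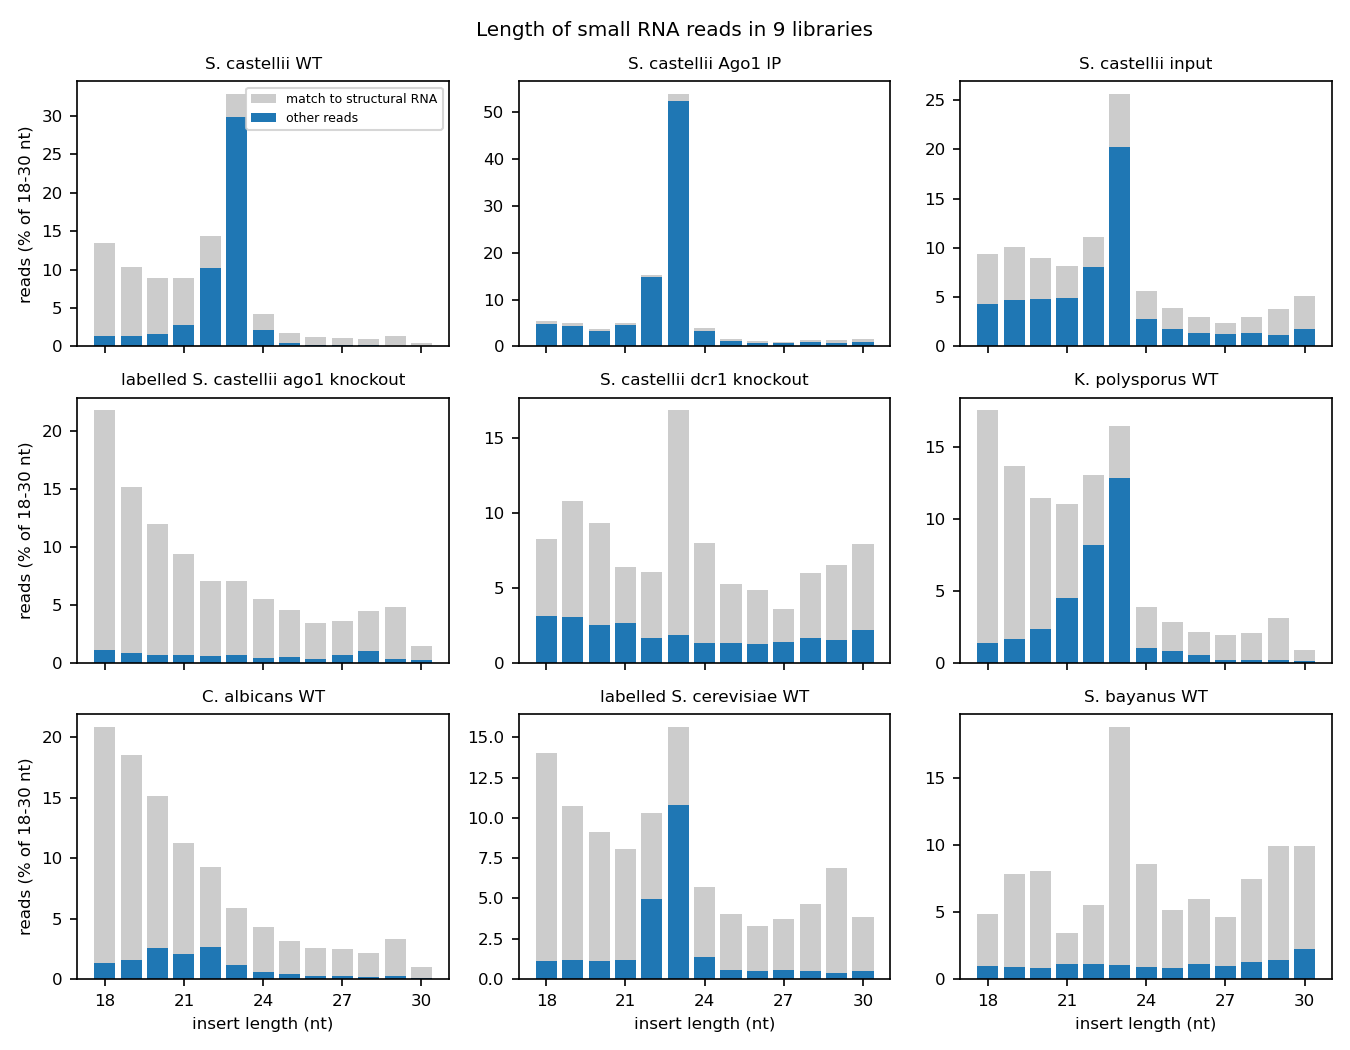
Share of small RNA reads (percent of all reads of 18 to 30 nt, vertical axis) at each insert length (nt, horizontal axis) in the 9 libraries, with matches to structural RNA in grey and other reads in blue; vertical scales differ between panels. Reads of 23 nt outside structural RNA dominate in S. castellii WT, where 23 nt reads were 32.8% of all small RNA reads, and are few in the dcr1 knockout.

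The dcr1 knockout asked which small RNAs need Dicer. The 22 to 23 nt share was 22.9% (22.85 to 23.01) in the dcr1 knockout, 0.486 times that of WT (0.483 to 0.489), and with structural RNA left out it was 13.8% (13.6 to 13.9), 0.173 times that of WT (0.171 to 0.175). Against the input library the ratio with structural RNA left out was 0.284 (0.281 to 0.288). No 22 to 23 nt sequence among 7748 had a partner with 2-nt overhangs, which allows at most 0.0476% (upper 95% limit), or 0.0955% over the 3860 outside structural RNA. Partners at other offsets were near 0 as well, with a mean of 0.00242% and a highest value of 0.0258% over all reads. The 5′ U share of these reads outside structural RNA was 26.4% (25.9 to 26.8).

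Per sequence of 21 to 24 nt with at least 100 reads over both libraries, 95 of 290 were at least 4-fold lower in the dcr1 knockout than in WT and 177 at least 4-fold higher. Outside structural RNA 80 of 139 were lower and 55 higher, and among structural RNA sequences 15 of 151 were lower and 122 higher. The species origin of structural RNA reads in WT was not settled: 70.98% of its tRNA reads of 24 to 30 nt matched S. cerevisiae perfectly, against 35.4% in the dcr1 knockout. A set of 382 S. castellii-type rRNA and tRNA sequences had 1351 RPM in WT, 1544 RPM in Ago1 IP and 73585 RPM in the dcr1 knockout. Its sequences were chosen for their presence in the input and the dcr1 knockout, so the high value in the dcr1 knockout was built in. A low value, as in Ago1 IP, does not by itself show another species. With the origin not settled, the structural counts are not read as a change in S. castellii RNA. The sequence AGGATATGAAAGAAATGATGCTT had 0 reads in the dcr1 knockout and was 1938-fold lower than in WT with 0 set to 3 reads, and TGAGATTCGAGAAACATGCTGTT fell from 962 reads to 0. The highest ratio was that of TGCCTGTTTGAGCGTCATTTC, with 9186 reads in the dcr1 knockout and 3 in WT, a ratio of 789.9 (270.2 to 3831), and 1752 reads in the input and 498 in S. bayanus. Without up to 3 bases at 1 end it matched rRNA. Among the 55 higher sequences counted outside structural RNA, 15 matched structural RNA in this way and 3 matched mammalian microRNAs. The rRNA sequence GCGAAACTCAGGTGCTGCAATCT had 72499 reads against 44, and 12478 in the input and 77145 in S. bayanus. WT was also low against the input in 68 of 127 structural RNA sequences. Profiles used another set of 143 structural RNA sequences of any length, with at least 2000 reads summed over the libraries. These sequences are not independent replicates. The profiles correlated at -0.0436 between WT and the input and at 0.896 between the input and the dcr1 knockout. Whether choosing sequences by summed reads lowers the correlation of the shallower WT library was not tested. The median ratio over all 290 sequences was 9.37 and fell to 5.93 when scaled to reads outside 21 to 24 nt and to 3.67 when scaled by the median of 25 to 30 nt sequences, where 100 sequences were lower and 138 higher. Against the input the direction turned, with 414 of 694 sequences lower, 145 higher and a median ratio of 0.0336. Of the 694 sequences 379 had 0 reads in the dcr1 knockout, so that median depends on the 3 reads set for 0.

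Of the 115 overlap groups with at least 100 reads over both libraries, 85 were at least 4-fold lower in the dcr1 knockout than in WT and 28 at least 4-fold higher, at a median ratio of 0.00393, or 0.00249 when scaled to reads outside 21 to 24 nt. The group with the most reads, 655 nt long, fell from 12367 reads in WT to 8, and a group of 369 nt from 9499 reads to 2, a ratio of 5.4e-05 (6.6e-06 to 0.000196). An 843-nt group resembled the Y′ element helicase YEL077C of S. cerevisiae over 303 amino acids at 33.7% identity, and fell from 1626 reads to 0, at least 2101-fold lower. A group of 167 nt resembling the retrotransposon gene YIL082W-A fell from 2315 reads to 0, at least 2991-fold lower, and a group of 93 nt resembling YDR316W-B fell from 1230 reads to 0. The highest ratio was that of a 33-nt group with 11067 reads in the dcr1 knockout, 5 in WT, 2156 in the input and 2297 in S. bayanus. The next, of 32 nt, had 1994, 0, 370 and 2121 reads, and then one of 61 nt had 1617, 0, 4917 and 0. Whether structural RNA missed by the rule makes up the higher groups was not tested. Against the input library, 187 of 234 groups were at least 4-fold lower and 11 at least 4-fold higher, with a median ratio of 0.0187, or 0.0148 when scaled to reads outside 21 to 24 nt. The dcr1 knockout and WT libraries also differed in size markers and in adapter base calls, which the dcr1 knockout and the input shared in part, and each came from another strain. Uncalled bases were in 41.1% of raw reads in WT, against 0.247% in the dcr1 knockout and 0.244% in the input.

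The ago1 knockout asked which small RNAs need Argonaute. In the library labelled ago1 knockout the 22 to 23 nt share was 14.1% (13.9 to 14.3), 0.299 times that of WT (0.294 to 0.304), and with structural RNA left out 15.8% (14.98 to 16.6), 0.198 times that of WT. Of 107 sequences 82 were at least 4-fold lower than in WT and 8 at least 4-fold higher. All 80 sequences outside structural RNA were lower, as were all 86 overlap groups with enough reads, at a median ratio of 0.0185. The median over the 107 sequences was 0.0566, and 0.0316 or 0.0149 when scaled to reads outside 21 to 24 nt or by 25 to 30 nt sequences. The sequence AGGATATGAAAGAAATGATGCTT had 1 read, a ratio of 0.00179 (4.52e-05 to 0.00997), and the 655-nt group had 41 reads. None of 1922 sequences had a partner with 2-nt overhangs, but only 80 of these lay outside structural RNA, where 0 allows up to 4.51% (upper 95% limit). A count of 0 allows 30.6 RPM in this library, the highest such limit of the 9, and its sequences contradict its species label.

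With the library labelled S. cerevisiae WT in its place, the ratio of 22 to 23 nt shares to S. castellii WT was 0.550. The difference was smaller with structural RNA left out, at 63.7% against 79.6% in S. castellii WT, which was then 1.249 times as high (1.237 to 1.261). Of 118 overlap groups, 48 were at least 4-fold lower than in S. castellii WT, 2 were at least 4-fold higher, and the median ratio was 0.341, or 0.224 when scaled to reads outside 21 to 24 nt. Of 247 sequences 82 were lower and 23 higher, and 141 and 6 when scaled by 25 to 30 nt sequences, which moved the median ratio from 0.666 to 0.204. The 655-nt group had 11821 reads there. Its 22 to 23 nt reads outside structural RNA started with U in 25.0% (24.6 to 25.3), against 47.6% in S. castellii WT.

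**Figure D2:**
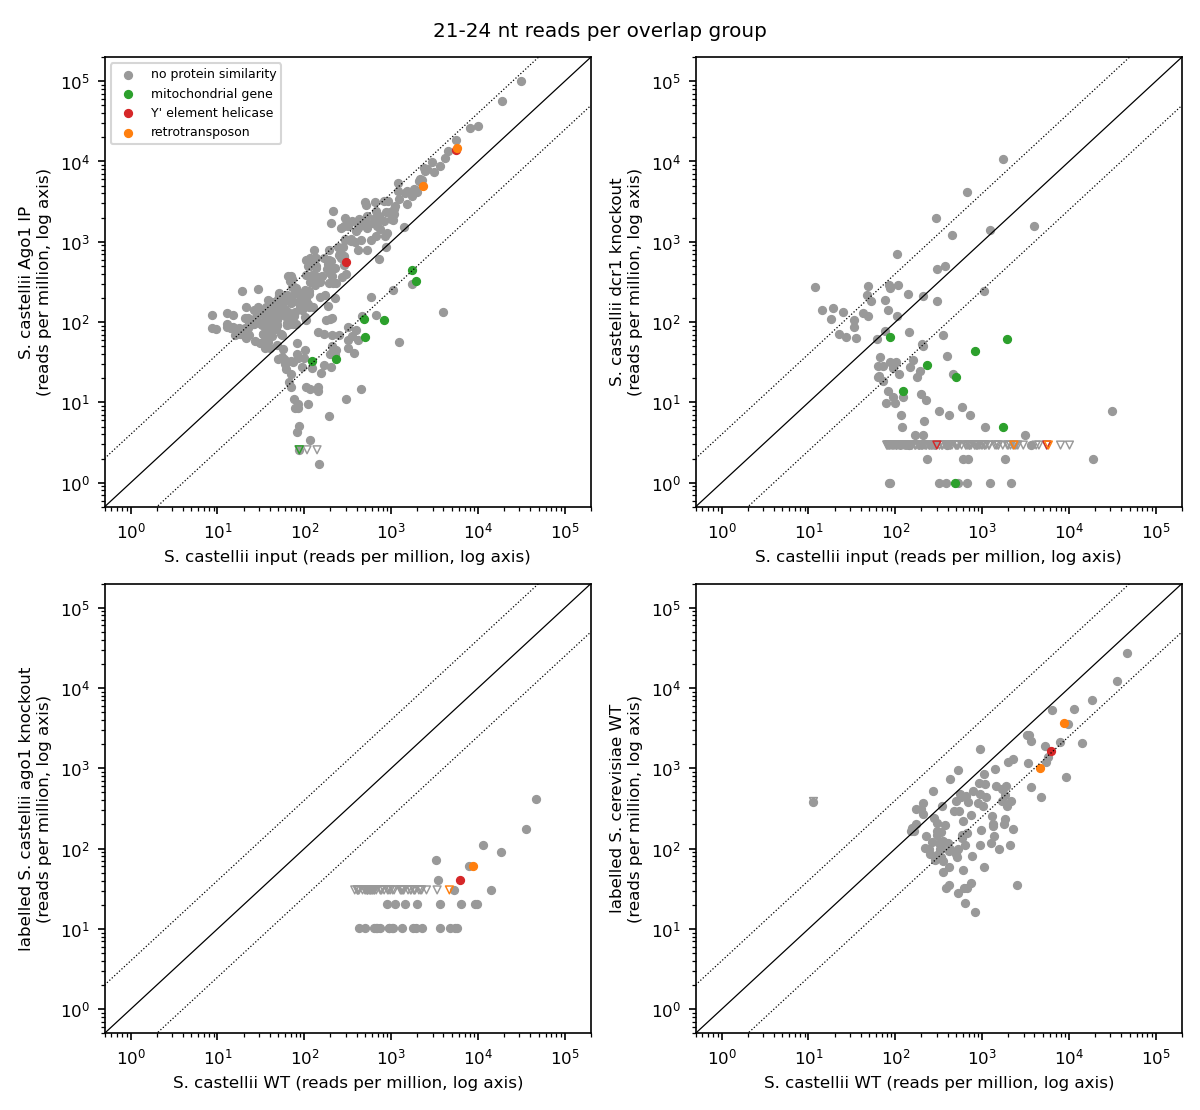
RPM of 21 to 24 nt reads in each overlap group with at least 100 reads over both libraries (log axes), for pairs of libraries; each point is 1 group, coloured by protein similarity, open triangles have 0 reads in 1 library and are drawn at the limit that 0 reads allow, the solid line marks equality and dotted lines 4-fold differences. Most groups lie far below equality in the dcr1 knockout and in the library labelled ago1 knockout, while in the library labelled S. cerevisiae WT 48 of 118 groups were at least 4-fold lower than in S. castellii WT and the median ratio was 0.341.

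The Ago1 IP against the input asked which RNAs Argonaute binds. The 22 to 23 nt share was 69.2% (69.2 to 69.3) in Ago1 IP and 36.6% (36.6 to 36.7) in the input, a ratio of 1.89 (1.88 to 1.896), and 1.504 with structural RNA left out. The 5′ U share of these reads outside structural RNA was 50.02% (49.9 to 50.1) in Ago1 IP and 41.8% (41.6 to 41.9) in the input. In Ago1 IP it was lower at other lengths, with 31.8% at 18 to 20 nt and 23.4% at 25 to 30 nt. The input had 32.1% and 31.9% at these lengths. Of 1893 sequences 809 were at least 4-fold higher in Ago1 IP and 143 at least 4-fold lower, with a median ratio of 3.53. Scaled to reads outside 21 to 24 nt, 1482 were higher and 101 lower with a median of 7.95, and scaled by 25 to 30 nt sequences 1653 were higher and 76 lower with a median of 15.4. Among the 107 structural RNA sequences 91 were lower and 5 higher, and the lowest ratio was that of the tRNA sequence TTTAATGGTTAGAATGGGCGCTT, with 2 reads against 1868, a ratio of 0.00115 (0.000139 to 0.00417).

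The sequences with the highest and next highest ratios, 71.3 (27.5 to 263.6) and 63.1 (21.3 to 309.1), matched mammalian microRNAs and are not read as RNA of S. castellii. The next was TGCGACTGCCTCCATTTTTTTT, with 147 reads in Ago1 IP against 4, a ratio of 39.5 (15.1 to 147.1). Reads that hold the core of 1 of 17 mammalian microRNAs made up 0.166% of Ago1 IP, 0.117% of the dcr1 knockout, 0.0995% of S. bayanus and 0.00438% of the input, and 4 of the 804 higher sequences outside structural RNA were of this kind. The most abundant sequence in Ago1 IP, TAATTATTTTGTATTGATTAGAC, had 8263 reads there and 2389 in the input. Of 347 overlap groups, 62 were at least 4-fold higher and 46 at least 4-fold lower, with a median ratio of 2.46. Scaled to reads outside 21 to 24 nt, 229 were higher and 20 lower, while with reads of 18 to 30 nt counted 54 were higher and 78 lower, which turned the majority. The 655-nt group had 118587 reads against 39269. Groups resembling retrotransposons had a median ratio of 2.34 and those resembling Y′ helicases one of 2.20, while 8 groups resembling mitochondrial genes had one of 0.157. A partner with 2-nt overhangs was found for 18.0% (17.6 to 18.4) of sequences in Ago1 IP, below the highest other offset at 18.4%, though with the library thinned and structural RNA left out the share was 18.7%, above the highest other offset at 16.9%. In the input such a partner was found for 19.3% (18.9 to 19.7), above the highest other offset at 17.1%. Scaled to reads outside 21 to 24 nt, the median ratio of all groups rose to 5.53 and that of the mitochondrial groups to 0.354, so the direction of the latter did not change.

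**Figure D3:**
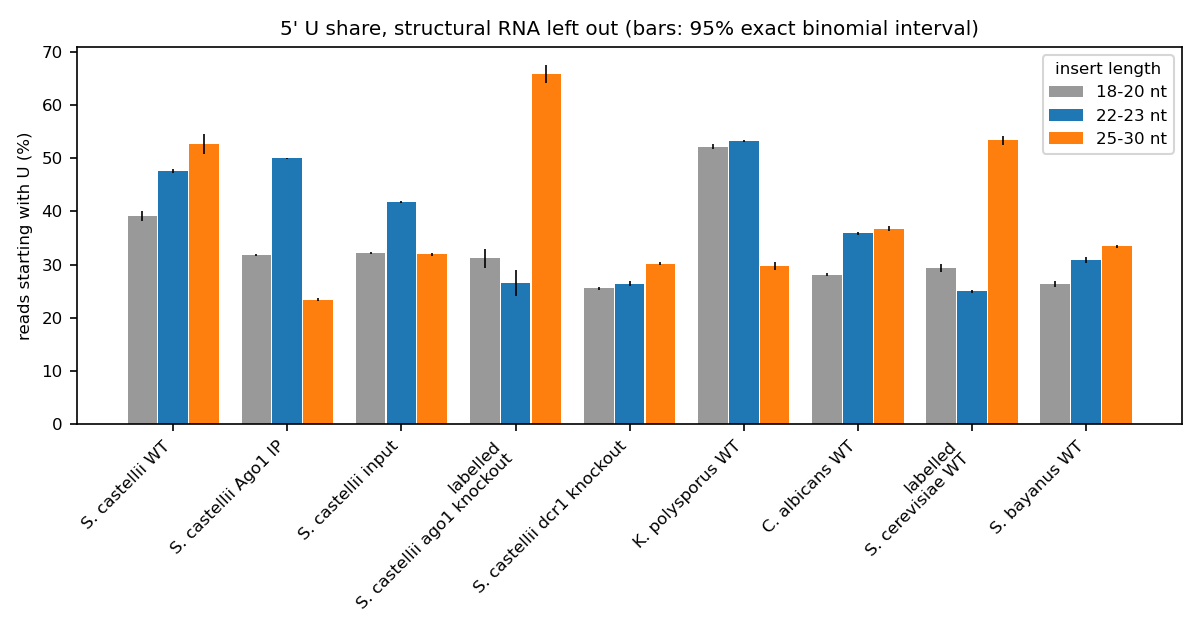
Share of reads that start with U (percent, vertical axis) in 3 length classes per library, with matches to structural RNA left out; error bars are exact 95% binomial intervals for 1 library each. At 22 to 23 nt the share was 50.02% in Ago1 IP, 47.6% in S. castellii WT and 53.2% in K. polysporus, and 25.0% in the library labelled S. cerevisiae WT. In S. castellii WT the share at 25 to 30 nt was 52.6%, and in Ago1 IP it was 23.4%.

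The species comparison asked which other yeasts make such small RNAs. In K. polysporus the 22 to 23 nt share was 29.5% (29.4 to 29.6), and 61.7% (61.6 to 61.9) with structural RNA left out, 4.28 times that of S. bayanus (4.22 to 4.34), against 1.22 times with all reads. These reads started with U in 53.2% (53.0 to 53.5), against 52.2% at 18 to 20 nt and 29.7% at 25 to 30 nt outside structural RNA. A partner with 2-nt overhangs was found for 15.3% (14.8 to 15.7) of sequences, against a mean of 13.3% and a highest value of 14.6% over other offsets. Its reads formed 399 overlap groups, the longest of 488 nt with 38396 reads, of which 2 resembled retrotransposons and 1 a Y′ helicase.

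In C. albicans the share was 15.2% (15.2 to 15.3), and 29.0% (28.8 to 29.2) with structural RNA left out, 2.01 times that of S. bayanus (1.98 to 2.04). With all reads it was 0.626 times that of S. bayanus (0.623 to 0.630), so the direction depended on the processing, and 74.5% of tRNA reads of 24 to 30 nt in this library matched S. cerevisiae perfectly, so the species origin of its structural RNA was not settled. Outside structural RNA, 19.996% of reads were of 22 nt, 19.4% of 20 nt, 15.3% of 21 nt and 8.99% of 23 nt. A partner with 2-nt overhangs was found for 9.55% (9.16 to 9.95) of sequences, against a mean of 4.76% and a highest value of 8.79% over other offsets. With the library thinned and structural RNA left out, the share was 6.77% (4.24 to 10.2) of 310 sequences, below the highest other offset at 7.10%. Its reads formed 117 overlap groups, the longest of 286 nt with 10903 reads, and none resembled an S. cerevisiae protein.

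In S. bayanus the share was 24.3% (24.2 to 24.4), and 14.4% (14.2 to 14.6) with structural RNA left out, and none of 5368 sequences had a partner with 2-nt overhangs, which allows at most 0.0687% (upper 95% limit), or 0.164% over the 2252 outside structural RNA. At other offsets the highest value over all reads was 0.0186%. The library labelled S. cerevisiae WT had a share of 25.97% (25.8 to 26.1), and 63.7% (63.5 to 64.0) with structural RNA left out, and 17.4% (16.7 to 18.1) of its sequences had a partner with 2-nt overhangs, against a mean of 12.1% and a highest value of 15.1% over other offsets. The K. polysporus and C. albicans shares were 1.14 and 0.586 times that of this library, and 0.969 (0.960 to 0.977) and 0.455 times with structural RNA left out, where the direction for K. polysporus turned. The library labelled ago1 knockout had a share of 14.1% (13.9 to 14.3), and 15.8% (14.98 to 16.6) with structural RNA left out. Both were below the K. polysporus and C. albicans shares, so with the labels exchanged the direction for C. albicans turns. Growth temperature, 25 °C or 30 °C, differed with species, and the sequences of the library labelled S. cerevisiae WT contradict that label.

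Structural RNA took most reads in several libraries, and its species origin was not settled in S. castellii WT, K. polysporus, C. albicans and the libraries labelled ago1 knockout and S. cerevisiae WT. rRNA made up 71.1% of small RNA reads in the library labelled ago1 knockout, 48.3% in the dcr1 knockout, 40.6% in S. castellii WT, 27.5% in the input and 6.51% in Ago1 IP. tRNA made up 25.97% in the dcr1 knockout, 13.9% in the input, 8.82% in S. castellii WT and 0.945% in Ago1 IP. snRNA and snoRNA together made up 0.312% in S. castellii WT and 1.21% in S. bayanus. Of 980 overlap groups of S. castellii, 15 resembled a protein, and none of these a ribosomal protein, glycolysis, histone or heat shock gene. With 45864 nt over all groups, short groups may have missed the blastx threshold, so this does not show that such RNA was absent. In the S. castellii input, 2186 reads matched 118 of the 138 S. cerevisiae ribosomal protein genes. Glycolysis genes had 883 reads there, histone genes 22 and heat shock genes 221. Ribosomal protein matches numbered 18 reads in S. castellii WT, 273 in Ago1 IP and 170 in the dcr1 knockout. Matches to S. cerevisiae genes in the library labelled ago1 knockout numbered 26 reads for 138 ribosomal protein genes, 17 for 16 glycolysis genes, 0 for 8 histone genes and 4 for 19 heat shock genes. Among perfect genome matches there, 774 reads were sense and 65 antisense to protein-coding genes, 588 were intergenic and 73 lay in Ty elements or their repeats.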

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

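The tests of exchanged labels, carried-over reads, background, conservation, added RNA, library batch and structural RNA were chosen only after the result was seen. Sets of libraries also stood out for reads that no comparison used, each above the limit that a count of 0 allows. The adapter was read with C in place of A in 24.6% of raw reads in Ago1 IP, 19.5% in the input, 20.6% in the dcr1 knockout and 17.7% in S. bayanus, against 2.02% in S. castellii WT and 3.88% in K. polysporus. Synthetic size markers made up 33.5% of inserts of 18 to 30 nt in Ago1 IP, 4.81% in the input, 44.7% in the library labelled ago1 knockout, 32.4% in the dcr1 knockout, 28.4% in the library labelled S. cerevisiae WT and 29.02% in S. bayanus. In S. castellii WT they made up 0.0358%. No explanation of these reads was tested.

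The sequences of the library labelled ago1 knockout and of the library labelled S. cerevisiae WT went against their species labels. An exchange of their labels may explain this, since S. castellii overlap groups held 66.3% of 21 to 24 nt reads outside structural RNA in the library labelled S. cerevisiae WT and 10.1% in the library labelled ago1 knockout, no more than the 12.3% of S. bayanus. That last bound replaced a first one of 10%, which the value had narrowly missed. The set of 382 S. castellii-type rRNA and tRNA sequences was chosen without use of either library. It had 2814 RPM in the library labelled S. cerevisiae WT and 20.4 RPM in the library labelled ago1 knockout, against 1351 RPM in S. castellii WT. A Saccharomyces-type set of 279 sequences, chosen for presence in S. bayanus, had 989 RPM in the former library and 8524 RPM in the latter. Against reads carried over from S. castellii WT, Ago1 IP or the input, only 25.0% of the 22 to 23 nt reads in these groups started with U in the library labelled S. cerevisiae WT, where the lowest of those 3 libraries had 43.4%, and against S. cerevisiae background alone, intergenic S. cerevisiae matches in the library labelled ago1 knockout were 13.1 times as frequent as in the highest of S. castellii WT, K. polysporus and C. albicans (lower limit 10.9). A wrong label set on each library by itself stays open, and no biological explanation was tested.

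Reads of 24 to 30 nt matched intergenic S. cerevisiae DNA at 156.2 RPM in C. albicans and 99.98 RPM in K. polysporus, against 22.3 RPM (14.8 to 32.2) in the S. castellii input and 60.9 RPM (34.8 to 98.9) in S. castellii WT, which shows the signal too. Conservation between species is argued against by the ratio of C. albicans to that input, 7.01 (lower limit 4.76). S. cerevisiae RNA or reads added during preparation or sequencing may be the source, since 70.98% of tRNA reads of 24 to 30 nt matched S. cerevisiae perfectly in S. castellii WT and 35.4% in the input. Neither a step at which they were added nor a biological explanation was tested, and if they were added, the structural RNA values of these libraries, and ratios that count them, mix species.

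The dcr1 knockout had fewer 22 to 23 nt reads than S. castellii WT. Library batch was tested with the input, which shares the adapter calls: the median ratio over overlap groups was 0.0187, against 1.09 for WT to the input. The input differed from the dcr1 knockout in size markers (4.81% against 32.4%) and in mammalian microRNA reads (0.00438% against 0.117%). The values therefore argue only against a batch marked by the adapter calls, and another difference in preparation stays open. Abundant structural RNAs are argued against too, since the ratio of shares without them was 0.173, below 0.486 with all reads. Loss of the Dicer gene cannot be told apart from other differences of this single library and its strain: 79.9% (74.2 to 84.9) of groups were at least 4-fold lower than in the input, but 25.4% (19.997 to 31.5) were so in WT, where the bound written beforehand was 25%, inside that interval. Both intervals treat overlap groups as independent draws, which was not tested, so they may be too narrow. Loss of the Dicer gene stays open as a biological explanation.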

How the results depend on the processing

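The alternatives chosen only after the data were seen were leaving out conserved sequences (found in at least 4 of the 5 species), keeping size-marker reads, keeping inserts with uncalled bases, allowing 1 adapter mismatch, keeping sequences with 1 read for pairing, leaving out structural RNA in ratios, leaving out mammalian microRNAs, exchanging labels, and 19-base overlaps. Of the alternative values, 95 stayed within the counting interval of their main value or, for counts, within 1.5 times of it, and 196 moved further. The ratios of shares of the dcr1 knockout and the library labelled ago1 knockout to WT and of Ago1 IP to the input stayed on their side of 1 in the alternatives run, but some majorities of lower or higher counts turned, as given below. Counting intervals are narrow at these depths, and except where a sentence below states it the cause was not tested. No paired analysis was possible because each group had 1 library. In each alternative run, the 22 to 23 nt share was higher in Ago1 IP than in the input, and lower in the dcr1 knockout and in the library labelled ago1 knockout than in S. castellii WT. The order of C. albicans and S. bayanus did change: C. albicans was lower with all reads and higher with distinct sequences, without the 10 most abundant sequences, without structural RNA, without conserved sequences and in the window of 20 to 24 nt. K. polysporus was above the library labelled S. cerevisiae WT except without structural RNA and with all trimmed reads as denominator. In both of these cases K. polysporus was above the library labelled ago1 knockout, so the exceptions rest on the species label.

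Counting each distinct sequence once gave 22 to 23 nt shares of 42.1% in S. castellii WT, 53.2% in Ago1 IP, 28.7% in the input, 15.3% in the dcr1 knockout and 16.9% in the library labelled ago1 knockout. The shares then were 27.97% in the library labelled S. cerevisiae WT, 35.8% in K. polysporus, 20.4% in C. albicans and 12.5% in S. bayanus. The same choice gave 5′ U shares of 40.5% in S. castellii WT, 44.7% in Ago1 IP, 35.7% in the input, 26.7% in the dcr1 knockout and 27.6% in the library labelled ago1 knockout. For other libraries these were 27.3% in the library labelled S. cerevisiae WT, 44.9% in K. polysporus, 31.5% in C. albicans and 28.6% in S. bayanus.

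Without sequences of 1 read the 22 to 23 nt shares were 48.8% in S. castellii WT, 70.2% in Ago1 IP, 39.6% in the input, 23.4% in the dcr1 knockout and 13.1% in the library labelled ago1 knockout. Beside these stood 25.7% in the library labelled S. cerevisiae WT, 28.1% in K. polysporus, 14.4% in C. albicans and 25.2% in S. bayanus. The 5′ U shares without them were 46.6% in S. castellii WT, 50.2% in Ago1 IP, 42.5% in the input, 32.8% in the library labelled ago1 knockout and 25.7% in the library labelled S. cerevisiae WT. Further 5′ U shares were 48.8% in K. polysporus and 42.7% in S. bayanus.

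Leaving out the 10 most abundant sequences gave shares of 46.4% in S. castellii WT, 68.8% in Ago1 IP, 13.8% in the dcr1 knockout, 13.8% in the library labelled ago1 knockout and 26.3% in the library labelled S. cerevisiae WT. It also gave 30.4% in K. polysporus, 15.8% in C. albicans and 13.7% in S. bayanus. Their removal left 5′ U shares of 43.9% in S. castellii WT, 48.3% in Ago1 IP, 40.2% in the input, 25.9% in the dcr1 knockout and 26.6% in the library labelled ago1 knockout. Next to these stood 25.7% in the library labelled S. cerevisiae WT.

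Without structural RNA the 22 to 23 nt shares were 79.6% in S. castellii WT, 72.8% in Ago1 IP, 48.4% in the input, 13.8% in the dcr1 knockout and 15.8% in the library labelled ago1 knockout. In the remaining libraries they were 63.7% in the library labelled S. cerevisiae WT, 61.7% in K. polysporus, 28.98% in C. albicans and 14.4% in S. bayanus. The 5′ U shares without structural RNA were 47.6% in S. castellii WT, 41.8% in the input, 26.4% in the dcr1 knockout, 26.5% in the library labelled ago1 knockout and 24.96% in the library labelled S. cerevisiae WT. In the rest the 5′ U shares were 53.2% in K. polysporus, 35.9% in C. albicans and 30.8% in S. bayanus. Sequences with a partner at 2-nt overhangs then made up 29.3% in S. castellii WT, 23.4% in the input, 29.3% in the library labelled S. cerevisiae WT, 21.2% in K. polysporus and 24.1% in C. albicans.

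In the wider window of 21 to 23 nt, which adds reads by construction, the shares were 56.1% in S. castellii WT, 74.2% in Ago1 IP, 44.8% in the input, 29.4% in the dcr1 knockout and 23.5% in the library labelled ago1 knockout. The other shares in that window were 34.02% in the library labelled S. cerevisiae WT, 40.5% in K. polysporus, 26.5% in C. albicans and 27.8% in S. bayanus.

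A window of 20 to 24 nt, which adds more reads by construction, gave 69.3% in S. castellii WT, 81.7% in Ago1 IP, 59.5% in the input, 46.7% in the dcr1 knockout and 40.9% in the library labelled ago1 knockout. It further gave 48.8% in the library labelled S. cerevisiae WT, 55.8% in K. polysporus, 45.9% in C. albicans and 44.3% in S. bayanus.

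With all trimmed reads of 1 to 30 nt as denominator, a larger total by construction, the shares were 36.1% in S. castellii WT, 42.6% in Ago1 IP, 22.05% in the input, 11.9% in the dcr1 knockout and 9.29% in the library labelled ago1 knockout. For other species labels they were 20.6% in the library labelled S. cerevisiae WT, 20.1% in K. polysporus, 10.1% in C. albicans and 17.9% in S. bayanus.

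Leaving out conserved sequences gave 22 to 23 nt shares of 68.4% in S. castellii WT, 70.7% in Ago1 IP, 41.6% in the input, 14.4% in the dcr1 knockout and 16.04% in the library labelled ago1 knockout. Shares elsewhere were 45.3% in the library labelled S. cerevisiae WT, 48.2% in K. polysporus, 21.1% in C. albicans and 12.9% in S. bayanus. Without conserved sequences the 5′ U shares were 46.9% in S. castellii WT, 49.6% in Ago1 IP, 26.3% in the library labelled ago1 knockout, 24.9% in the library labelled S. cerevisiae WT and 51.4% in K. polysporus. Also changed were 5′ U shares of 32.9% in C. albicans and 39.7% in S. bayanus. Partners at 2-nt overhangs were then found for 27.7% in S. castellii WT, 21.1% in the input, 25.4% in the library labelled S. cerevisiae WT, 18.3% in K. polysporus and 12.5% in C. albicans.

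Keeping size-marker reads, which have lengths outside the window, lowered the shares to 46.1% in Ago1 IP, 34.9% in the input, 15.6% in the dcr1 knockout, 7.84% in the library labelled ago1 knockout and 18.7% in the library labelled S. cerevisiae WT. It lowered them to 17.4% in S. bayanus.

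Inserts with uncalled bases, when kept, gave 46.2% in S. castellii WT and 29.7% in K. polysporus.

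Allowing 1 adapter mismatch gave shares of 62.8% in Ago1 IP, 36.3% in the input, 20.4% in the dcr1 knockout, 14.4% in the library labelled ago1 knockout and 26.5% in the library labelled S. cerevisiae WT. Elsewhere it gave 29.8% in K. polysporus, 15.3% in C. albicans and 21.6% in S. bayanus.

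With at least 5 reads per sequence the share with a partner at 2-nt overhangs was 21.5% in S. castellii WT, 20.5% in Ago1 IP, 22.03% in the input, 14.7% in the library labelled S. cerevisiae WT and 14.6% in K. polysporus. Other libraries had 6.53% in C. albicans. Keeping sequences with 1 read, it was 15.97% in S. castellii WT, 13.5% in Ago1 IP, 13.1% in the input, 13.8% in the library labelled S. cerevisiae WT and 12.4% in K. polysporus. Then it was 7.27% in C. albicans. Thinning each library to the same number of reads gave 18.99% in S. castellii WT, 14.6% in the input, 12.2% in the library labelled S. cerevisiae WT, 11.8% in K. polysporus and 1.12% in C. albicans. Of the sequences with a perfect S. cerevisiae genome match in the library labelled S. cerevisiae WT, 0 had such a partner, and 15.5% of its matching reads were of 22 to 23 nt. Thinning matched total reads only: outside structural RNA it left 310 sequences in C. albicans, 2673 in K. polysporus and 4208 in S. castellii WT, so these shares do not compare libraries at equal usable depth. In the dcr1 knockout the share with a partner was 0 under all 6 alternatives run, and in the library labelled ago1 knockout and in S. bayanus it reached at most 0.116% and 0.014%.

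Counts of 21 to 24 nt sequences at least 4-fold apart were 95 lower and 177 higher for the dcr1 knockout against WT, 82 lower and 8 higher for the library labelled ago1 knockout against WT and 143 lower and 809 higher for Ago1 IP against the input. From 30 reads over both libraries, which tests more sequences by construction, they were 603 lower and 425 higher for the dcr1 knockout against WT, 462 lower and 37 higher for the library labelled ago1 knockout against WT and 712 lower and 2279 higher for Ago1 IP against the input. Scaling to reads outside 21 to 24 nt gave 97 lower and 163 higher for the dcr1 knockout against WT, 84 lower and 4 higher for the library labelled ago1 knockout against WT and 101 lower and 1482 higher for Ago1 IP against the input. Scaling by the median ratio of 25 to 30 nt sequences gave 100 lower and 138 higher for the dcr1 knockout against WT, 88 lower and 1 higher for the library labelled ago1 knockout against WT and 76 lower and 1653 higher for Ago1 IP against the input. A 2-fold threshold, which passes more sequences by construction, gave 98 lower and 181 higher for the dcr1 knockout against WT, 84 lower and 13 higher for the library labelled ago1 knockout against WT and 181 lower and 1417 higher for Ago1 IP against the input. Without structural RNA, fewer sequences were tested, with 80 lower and 55 higher for the dcr1 knockout against WT, 80 lower and 0 higher for the library labelled ago1 knockout against WT and 52 lower and 804 higher for Ago1 IP against the input. Without mammalian microRNAs all 6 counts stayed within 1.5 times, with 174 higher for the dcr1 knockout against WT and 805 higher for Ago1 IP against the input. Whether more sequences were lower or higher in the dcr1 knockout therefore depended on the minimum, on structural RNA and on the comparator.

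For overlap groups the counts were 85 lower and 28 higher for the dcr1 knockout against WT, 86 lower and 0 higher for the library labelled ago1 knockout against WT and 46 lower and 62 higher for Ago1 IP against the input. From 30 reads, which tests more groups by construction, they were 168 lower and 51 higher for the dcr1 knockout against WT, 167 lower and 1 higher for the library labelled ago1 knockout against WT and 94 lower and 164 higher for Ago1 IP against the input. Scaled to reads outside 21 to 24 nt they were 85 lower and 24 higher for the dcr1 knockout against WT, 86 lower and 0 higher for the library labelled ago1 knockout against WT and 20 lower and 229 higher for Ago1 IP against the input. With reads of 22 to 23 nt they were 81 lower and 17 higher for the dcr1 knockout against WT, 81 lower and 0 higher for the library labelled ago1 knockout against WT and 33 lower and 66 higher for Ago1 IP against the input. With reads of 18 to 30 nt they were 91 lower and 65 higher for the dcr1 knockout against WT, 92 lower and 1 higher for the library labelled ago1 knockout against WT and 78 lower and 54 higher for Ago1 IP against the input, so more groups were lower than higher in Ago1 IP. Overlaps of 19 bases left all 6 counts within 1.5 times of the main ones.

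With the input library as comparator the ratio of 22 to 23 nt shares was 0.626 for the dcr1 knockout and 0.385 for the library labelled ago1 knockout. Sequences then numbered 414 lower and 145 higher for the dcr1 knockout and 280 lower and 14 higher for the library labelled ago1 knockout. Groups numbered 187 lower and 11 higher for the dcr1 knockout and 164 lower and 0 higher for the library labelled ago1 knockout. Without structural RNA the ratios of shares were 0.173 for the dcr1 knockout to WT, 0.198 for the library labelled ago1 knockout to WT and 1.504 for Ago1 IP to the input. With the labels of the library labelled ago1 knockout and the library labelled S. cerevisiae WT exchanged, the ratio of shares to WT was 0.550 in place of 0.299, 82 lower and 23 higher among sequences, and 48 lower and 2 higher among groups.

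Some alternatives changed nothing by construction. No read had several loci, so keeping only reads with 1 locus left every group count as it was. Pairing already used distinct sequences with at least 2 reads, so counting distinct sequences or leaving out sequences with 1 read gave no other value there. Perfect genome matches were used only for the library labelled S. cerevisiae WT, since no genome of another species was given. The denominator of reads of any length was run as trimmed reads of 1 to 30 nt, since longer inserts are not seen in 36-nt reads. Depth limits the library labelled ago1 knockout most, with 98076 small RNA reads.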

Other observations

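In this part the bound for related pairs was written before its test, while the groups resembling mitochondrial genes were named after their values were seen. In the input, 11 overlap groups resembling mitochondrial genes had 9685 reads of 18 to 30 nt, of which 67.2% were 23 nt long and 44.2% (43.2 to 45.2) were antisense to the similar gene. Ago1 IP had 1583 such reads, 76.9% of 23 nt and 52.4% (49.9 to 54.9) antisense. The dcr1 knockout had 939, of which 8.41% were of 23 nt and 2.77% (1.82 to 4.03) antisense. S. castellii WT had 6. Reads antisense to structural RNA genes numbered 4472 in Ago1 IP, with 83.9% of 22 to 23 nt, 438 in the input, 19 in S. castellii WT and 0 in the dcr1 knockout.

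Of 255 overlap groups with at least 100 reads in Ago1 IP, 149 had at least 90% of their reads on 1 strand and 75 had at least 25% on the lesser strand. Among the 149, 37 related pairs were found by sequence, and with each group turned to its main strand 34 of these, 91.9% (78.1 to 98.3), matched in opposite orientation at a median identity of 87.5%. The pairs involved 53 groups, 35.6% of the 149. The interval treats pairs as independent, though groups recur among them, so it may be too narrow for the bound given next. Inverted repeats transcribed into imperfect hairpins may be the source of these groups, a hypothesis whose bound of over 60% was written before the test. Whether paired groups lie near each other was not analysed here, since no S. castellii genome was given.

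In K. polysporus 189 groups had at least 100 reads, 85 of them with at least 90% on 1 strand and 69 with at least 25% on the lesser strand. The group with the most reads had 48.1% on 1 strand. In C. albicans the corresponding numbers were 48, 9 and 26. All 30 such groups of the dcr1 knockout had at least 90% of their reads on 1 strand.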
